A study of Mus musculus with 16 samples.

How the data were processed

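RNA was measured by sequencing in 16 libraries of aorta or liver from female C57BL/6 mice, per the labels. The mice were ovariectomized at 6 to 7 weeks of age and tissue was collected 1 week later. Aortas, or pieces cut from the tip of the major liver lobe, were then kept in culture medium for 4 h with 10 nM estradiol (E2, the main natural estrogen) or with ethanol vehicle. This gave 4 groups of 4 libraries. Per the labels, 8 libraries were made with an Ovation kit from 50 ng of RNA, on 2 sequencing instruments. The other 8 were made by poly-A selection with a TruSeq kit from 600 ng of RNA from 1 aorta or 1 piece of liver. The series text describes only a pair of replicates per condition, each holding tissue of 4 mice, which does not cover the TruSeq libraries as the labels describe them.

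The deposited table holds raw read counts per gene symbol. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.5 to mouse build mm9 and counted with HTSeq 0.4.5p7, and edgeR 3.4.2 was also named. The gene annotation, the strand setting and the read filters are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The deposited values were entered under the unit of estimated counts, which need not be whole, because each column ends with a percentage. Every gene value was a whole number, so rounding changed nothing. The table lists 24011 gene symbols. Another 8 lines name no gene and stayed out of library sizes and tests. They include reads in no annotated gene, which made up 48.0% to 75.2% of the reads of a library, and ambiguous reads, at 0.0452% to 0.523%. Reads counted to genes made up the remaining 24.7% to 51.6%.

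Each column name gives a tissue, a treatment and a suffix, o1, o2, n1 or n2. No label explains the suffix. Columns were therefore assigned to groups by tissue and treatment only, and libraries are called here by their suffix. The design fixed before the data were examined has a library batch of 3 levels, taken from the replicate numbers in the labels. On the columns its levels were o1, o2 and n. Whether o and n stand for the 2 kits is not stated in the sources used here. All of the following were fixed before the data were examined: the groups, the tests, the list of other settings to try, the 36 gene lists and the rule for naming genes.

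Counts were tested with edgeR 4.0.16 in R 4.3.3, by glmQLFit and glmQLFTest with TMM normalization. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15). The threshold was a Benjamini-Hochberg adjusted p under 0.05. E2 was compared with vehicle in the 8 libraries of each tissue, with the batch as a covariate. The difference between the E2 effects of the 2 tissues was tested as an interaction over all 16 libraries. Aorta was compared with liver in the 8 vehicle libraries, with an absolute log2 fold change over 1 as a further threshold. The n libraries were compared with the o libraries within each tissue, with treatment as a covariate and the same further threshold, and the E2 effects in n and o libraries were compared by an interaction. CPM are counts scaled to 1e6 reads on TMM library sizes. Errors are standard errors (SE) of log2 fold changes, or standard deviations (SD) of CPM over the 4 libraries of a group. The SE was derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. Pair differences are differences of log2(CPM + 1) between the E2 and the vehicle library of a suffix.

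Pairing was checked by the correlation across genes between the deviations from the group mean of the vehicle and the E2 library with the same suffix. The calls of both fits had been seen when this check was made. In aorta r was 0.85, 0.88, 0.89 and 0.87 for o1, o2, n1 and n2. In liver it was 0.90, 0.85, 0.91 and 0.87, and the highest correlation of n2 with a library of another suffix was 0.90. With the mean of the libraries of the same letter removed, r was 0.37 for o and 0.33 for n in aorta, and 0.25 and −0.06 in liver. The first set of correlations is dominated by the difference between o and n libraries, so it says little about pairs within a letter. The second was above 0.1 for both letters in aorta and not for n in liver. The suffix was therefore taken to pair the aorta libraries only, as an assumption that this check cannot settle. The batch already separates o1 from o2, so the block adds only the pairing of n1 and n2. Their deviations within a group are mirror images, so exchanging n1 and n2 of the E2 libraries would turn the sign of r. A positive r can thus arise without any pairing. The fit with all 4 suffixes as a replicate block is given in the results where it changes one of aorta. Blocked fits that include liver are given as values among the closing parts only.

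Gene lists (pathways, cell type markers and estrogen-related genes) held 968 symbols, of which 958 are in the table. Lists with at least 5 tested genes were tested with limma 3.58.1 on log2 CPM with a prior count of 2: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists. Camera compares a list with the other genes. Fry does not, and its mixed form tests whether members change in either direction. Counts adjusted over the list alone used the edgeR p-values of its members.

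Named genes follow a fixed rule. They are up to 10 genes per direction past the threshold with the largest changes, an average log2 CPM of 1 or more and the same direction in all 4 suffixes. Where fewer qualified, the genes with the smallest unadjusted p that met the other conditions were taken until 10 were reached, given as not past the threshold. Up to 4 members of each described list with the smallest p were added, and always Esr1, Esr2, Gper1, Pgr, Greb1 and Nrip1. For aorta against liver the tested markers of the tissue lists were taken. A few genes that the rule would name are not reported here.

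The settings to try, fixed with the design, were the replicate block, the letter o or n as the batch, no batch term, DESeq2 size factors, no filter, a filter at 1 CPM, DESeq2 1.42.0, robust quasi-likelihood, limma voom, an adjusted p under 0.10, o or n libraries alone, 1 fit over all libraries, and each library and each suffix left out. Added after the data had been seen were library totals without normalization factors, leaving out the ribosomal RNA gene Rn45s, a correction for transcript length and GC content, list tests without n2, list medians with library totals or DESeq2 size factors, and settings changed within the blocked fit. The correction removed from each library a spline trend with 5 degrees of freedom in each property. Lengths and GC contents were matched by symbol to GENCODE annotation of build GRCm38, which differs from mm9, so no coordinates are given. A length was found for 13632 of 13698 genes tested in aorta. Each comparison was also repeated with other splits of the same libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

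The fits were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes. These were drawn only from genes above a minimum mean count. With so many changed genes the adjusted threshold is easier to pass. The shares below may therefore overstate what is found among low genes or where few genes change. Without the block, 2% of genes changed 1.5-fold were called in the simulated aorta comparison (13445 genes tested). The share was 40% at 2-fold, 82% at 3-fold and 86% at 4-fold, with 5 false calls among 110. In the simulated liver comparison (11453 genes tested) these shares were 4%, 46%, 76% and 86%. With the block they were 2%, 40%, 82% and 84% in aorta, with 10 false calls among 114. That is a larger share of false calls than the threshold of 0.05 aims at, in a single simulation. The simulated means held no difference between n1 and n2. Library totals over genes ran from 3896733 to 19823982, and intervals or standard errors here cover 4 libraries per group.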

Results

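The data are read counts per gene in 16 libraries: 4 of aorta with vehicle, 4 of aorta with E2, 4 of liver with vehicle and 4 of liver with E2. Counts summed over genes ran from 6042073 to 19823982 in aorta with vehicle, from 6471319 to 16905441 in aorta with E2, and from 5210693 to 13078032 in liver with vehicle. In liver with E2 they ran from 3896733, in n2, to 11796977. The series title names tissue-specific gene regulation by estrogen, and the comparisons ask which genes respond to E2 in each tissue, and how the tissues differ.

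Tissue and library type set the libraries apart more than E2 did. The first principal component held 54.3% of the variance and separated aorta from liver, and the second held 32.8% and separated o from n libraries within each tissue. On the first, o libraries also scored higher than n libraries of the same tissue. On the second, liver also scored higher than aorta within each letter. Neither share of variance therefore belongs to tissue or to library type alone. Rn45s, a ribosomal RNA precursor, took 25.7% to 34.5% of counts in the o libraries of liver and at most 6.20% in every other library.

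**Figure D1:**
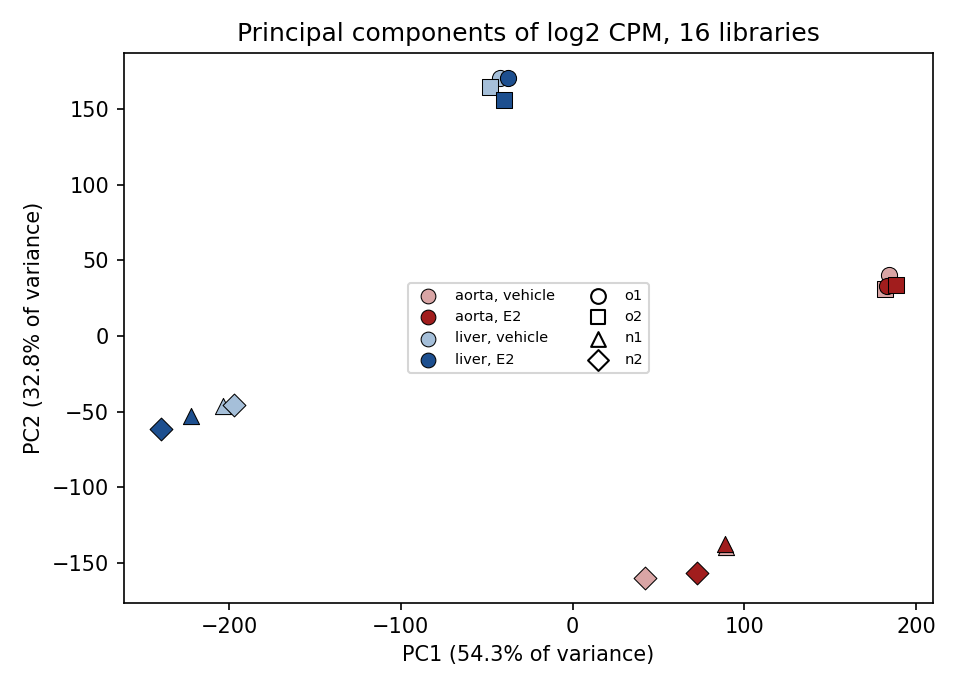
Scores of the 16 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; colours give tissue and treatment, and marker shapes give the suffix. Aorta lies to the right of liver, the o libraries lie above the n libraries of the same tissue.

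In aorta, E2 was compared with vehicle after 4 h. Pgr, which encodes the progesterone receptor and is a textbook target of estrogen receptor alpha, was 3.92-fold higher with E2, at 10.1 ± 3.43 CPM against 2.61 ± 1.15 CPM with vehicle (SD, n = 4), a log2 difference of 1.97 ± 0.23 (SE). Greb1, another classical estrogen target, stood at 2.29 ± 0.448 CPM against 0.496 ± 0.232 CPM, a log2 difference of 2.33 ± 0.45. Both genes were higher in 4 of 4 pairs. The replicate block compares the E2 library of each suffix with its own vehicle library, a pairing of n1 and n2 that no label states. With it, 12 genes passed the threshold: 11 rose and 1 fell. The gene that fell was Mmp3, a matrix metalloproteinase, at 80.8 ± 68.7 CPM against 192.6 ± 156 CPM, while Mmp19, another metalloproteinase, rose from 71.1 ± 31.3 to 193.5 ± 38.6 CPM.

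Each of these 12 genes moved the same way in all 4 pairs. In the blocked fit Klhl31 rose by 2.54 ± 0.34, Fbxo40 by 2.04 ± 0.31, Pgr by 1.97 ± 0.24, Tmod1 by 1.84 ± 0.20, Camk2b by 1.70 ± 0.22 and Mmp19 by 1.56 ± 0.21 (log2, SE, n = 4). Klhl31 and Fbxo40 are known from striated muscle, Tmod1 encodes tropomodulin, which caps actin filaments, and Camk2b encodes a calcium-dependent protein kinase. Caskin2, which encodes a scaffold protein, rose by 1.42 ± 0.14, Sytl5 by 1.29 ± 0.18, the myosin gene Myo18a by 1.24 ± 0.14, Desi2 by 1.20 ± 0.18 and Fam160a1 by 1.07 ± 0.16, and Mmp3 changed by −1.31 ± 0.17. Adjusted p ran from 0.00874 to 0.0390 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without the block no gene passed: 13698 genes were tested, the smallest adjusted p was 0.0898, for Caskin2 and Pgr, and 495 genes had an unadjusted p under 0.05, where 684.9 are expected by chance. With that design DESeq2 called 24 genes and limma voom called 0. Without the pair o2 the blocked fit called 0 genes, and without the pair n2 it called 35, all 12 among them.

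**Figure D2:**
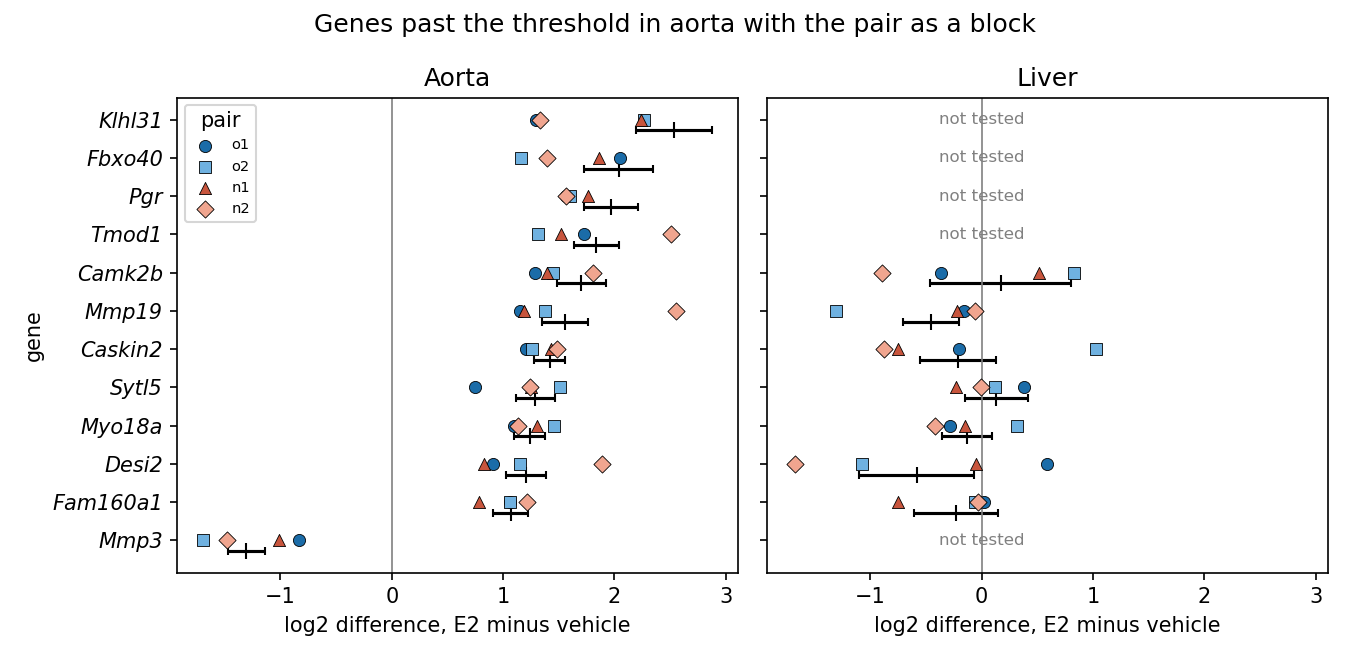
The 12 genes that passed the threshold in aorta with the replicate block (gene on the vertical axis). Markers give the log2(CPM + 1) difference, E2 minus vehicle, of each pair in aorta (left) and liver (right), and black bars give the blocked log2 fold change ± SE; in aorta all 4 pairs of every gene lie on one side of 0, from Klhl31 at 2.54 to Mmp3 at −1.31, and 5 of the genes were not tested in liver.

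Other genes that moved the same way in 4 of 4 pairs did not pass the threshold in either fit. Among them were Vstm2b (log2 2.06), Kcns3, a potassium channel subunit gene (1.61), Flrt1 (1.45), Reps2 (−1.56), Ttr, the transthyretin gene (−1.41), Cd55, a complement inhibitor gene (−0.91), Alb (−0.88), Slc35g2 (−0.77) and the enkephalin gene Penk (−0.76). The estrogen receptor gene Esr1 itself differed by 0.15 ± 0.23, Gper1 by −0.27 ± 0.49 and the coregulator gene Nrip1 by 0.30 ± 0.23. Esr2 had 3 counts over the vehicle libraries and 2 over the E2 libraries and was not tested.

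Of 35 tested genes known to respond to estrogen in uterus and breast, 20 were higher and 15 lower with E2 in aorta, with a median log2 difference of 0.04. None passed over all genes in the fit without the block. Adjusted over the list alone, 3 passed, all higher: Pgr, Greb1 and Aqp5, an aquaporin gene (log2 2.57 ± 0.50). Aqp5 was higher in the n pairs only and had no count in the o libraries. Fry's mixed test, which asks whether members change in either direction, passed for this list and for estrogen receptors and coregulators, which also holds Pgr (adjusted p 0.00113 for each, fry with Benjamini-Hochberg adjustment), and for hepatocyte genes (0.0495, and 0.0608 with the replicate block). Camera, which compares a list with other genes, did not pass for the estrogen-responsive list (adjusted p 0.0625, Benjamini-Hochberg) or for estrogen receptors and coregulators (0.0638). With the block fry's mixed test also passed for endothelial markers (0.0118) and fatty acid oxidation genes (0.0142), with Benjamini-Hochberg adjustment.

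Camera with the preset correlation passed for 12 of 36 lists in aorta, 4 higher and 8 lower with E2. With an estimated correlation and with fry's one-way test none of the 36 passed, and the adjusted p of the 12 lists lay between 0.473 and 0.614 with an estimated correlation. Inflammatory cytokines and leukocyte adhesion genes lay lower: 24 of 29 members were lower, 7 of them past the threshold adjusted over the list alone and 0 over all genes, with a median log2 difference of −0.30 (camera adjusted p 3.16e-08). Csf2 (−0.90 ± 0.21), Il6 (−0.78 ± 0.19), Cxcl5 (−0.99 ± 0.24) and Ccl2 (−0.65 ± 0.16), which encode cytokines that recruit or activate leukocytes, were lower in 4 of 4 pairs. Lipid genes lay higher. Of 21 fatty acid and triglyceride synthesis genes 20 were higher (median 0.38), among them Gpam (0.83 ± 0.29), Acacb (0.57 ± 0.21) and Fasn (0.49 ± 0.18), and of 25 fatty acid oxidation genes 18 were higher (median 0.19), among them Cpt1b (0.76), Ucp3 (1.07) and Ehhadh (0.99). Adipocyte markers (17 of 24 higher, median 0.08) and gluconeogenesis and insulin signalling genes (12 of 15, median 0.18) were the remaining lists that lay higher.

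Transcripts that mark liver cells lay lower in the E2 aortas. Of 24 hepatocyte genes tested in aorta 22 were lower (median −0.65), 7 of them past the threshold adjusted over the list alone and 0 over all genes, among them Ttr (−1.41 ± 0.26), Alb (−0.88 ± 0.19), Ahsg (−0.84 ± 0.22) and Apob (−0.97 ± 0.29). Alb stood at 109.6 ± 128 CPM in vehicle aortas and 66400 CPM in vehicle livers. Of 23 acute phase and coagulation genes 19 were lower (median −0.45), among them Serpinc1 (−1.57 ± 0.44) and Plg (−1.23 ± 0.36). All 20 lymphocyte markers were lower (median −1.33). Their median pair difference was −2.59 in n2 and 0.57 in o1. Without n2 the median of that list was 0.04. Macrophage markers (20 of 22 lower, median −0.19), adventitial fibroblast markers (17 of 19, median −0.13), cell cycle genes (25 of 31, median −0.22, and 0.08 without n2) and cytosolic ribosomal protein genes (29 of 32, median −0.44) completed the lists that lay lower. With the length and GC correction 11 lists passed, and the macrophage and gluconeogenesis lists did not. Across genes the aortic E2 effect rose with transcript length, with Spearman's rho 0.249, and genes are not independent replicates.

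**Figure D3:**
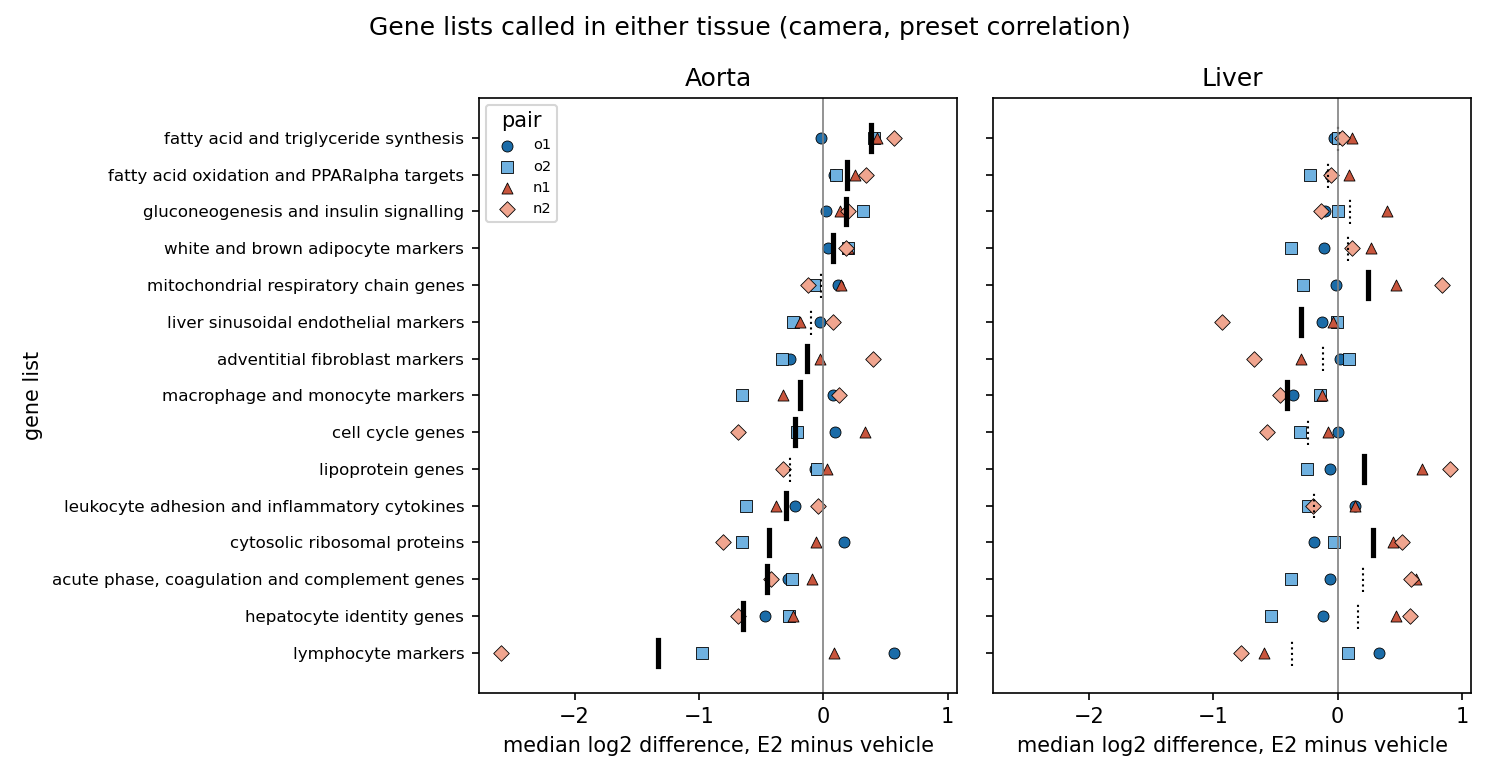
Gene lists that passed camera with a preset correlation in aorta (left) or liver (right). Markers give the median log2(CPM + 1) difference, E2 minus vehicle, of a list's members in each pair, and black bars the median fitted log2 fold change, thick where the list passed and dotted where it did not; the lymphocyte list in aorta has its lowest pair median, −2.59, in n2.

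In liver, no gene passed the threshold for E2 against vehicle. A pair here means a shared suffix only, since the suffix was not taken to pair the liver libraries. Most genes named below were picked for the same direction in all 4 suffixes, so that agreement is no separate evidence. The lowest unadjusted p belonged to Angptl4, which encodes an inhibitor of lipoprotein lipase and is a known target of PPAR receptors: it stood at 18.5 ± 8.30 CPM with E2 against 40.0 ± 16.2 CPM with vehicle (SD, n = 4), a log2 difference of −1.15 ± 0.23 (SE), lower in 4 of 4 pairs. Of 25 tested genes of fatty acid oxidation it was the one past the threshold adjusted over the list alone. Other genes lower in 4 of 4 pairs were Rfx4 (−1.58), Kif3c (−1.62), Tmem127 (−1.92), Siglece (−1.28), Synj2 (−1.10), the proliferation marker Mki67 (−1.02), the adenosine receptor gene Adora1 (−1.58), St6gal1 (−1.14) and AI607873 (−0.89). Genes higher in 4 of 4 pairs included Dcxr, which encodes xylulose reductase (0.99 ± 0.22), Trappc1 (0.93), AI462493 (0.95), Adck5 (0.87), Copz1 (0.92), Sssca1 (1.22), Tomm6 (0.80), the transcription factor gene Elf3 (1.82), Tmem160 (0.78) and Tmem19 (0.75).

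The test covered 11726 genes, and the smallest adjusted p was 0.939, for Angptl4 among others (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An unadjusted p under 0.05 was found for 502 genes, where 586.3 are expected by chance, and DESeq2 and limma voom called 0. Without a filter on low counts 6 genes passed. Esr1 differed by 0.02 ± 0.26 and Nrip1 by −0.13 ± 0.23, Pgr and Greb1 were too low to test (26 and 3 counts over the vehicle and E2 libraries for Pgr, 5 and 10 for Greb1), and the sulfotransferase gene Sult2a1 was at log2 1.48 ± 0.45, higher in 3 of 4 pairs. The o2 pair of Sult2a1 differed by −0.93, its log2 fold change ran from 0.32 (o libraries alone) to 2.33 (without the vehicle o2) over other settings, and it passed the threshold in 5 of 29 of them. Of 29 estrogen-responsive genes 15 were higher and 14 lower with E2 in liver (median 0.01), and Myc was at 0.71 ± 0.24, higher in 4 of 4 pairs; the adjusted p of fry's mixed test for this list was 0.954.

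Camera with the preset correlation passed for 5 of 35 lists in liver. With an estimated correlation and with fry none of the 35 passed. Macrophage markers lay lower in 22 of 23 members (median −0.41), among them Timd4 (−1.17 ± 0.37) and Vsig4 (−0.67 ± 0.23), known from Kupffer cells. All 17 liver sinusoidal endothelial markers lay lower (median −0.29), among them Fcgr2b (−0.58 ± 0.20) and Gpr182 (−0.51 ± 0.25). Mitochondrial respiratory chain genes (27 of 30 higher, median 0.24, with Uqcrfs1 at 0.46), cytosolic ribosomal protein genes (25 of 29, median 0.28, with Rpl14 at 0.70 and Rplp1 at 0.56) and lipoprotein genes (18 of 23, median 0.21, with Apom at 0.51) lay higher. With the length and GC correction none of the lists that lay higher passed. Without n2 only the macrophage list still passed of these 5: the sinusoidal endothelial, lipoprotein, mitochondrial and ribosomal lists did not. No member of the 5 lists passed, over all genes or adjusted over the list alone, and with an estimated correlation the adjusted p of each list was 0.914. In the o libraries alone the medians of the lists that lay higher were −0.16, −0.0039 and −0.13, against 0.62, 0.52 and 0.57 in the n libraries. Across genes the liver E2 effect fell with transcript length, with Spearman's rho −0.292.

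The difference between the E2 effects in aorta and liver was tested directly. No single gene passed. The genes with the smallest p and a higher effect in aorta in all 4 suffixes were Mmp19 (log2 difference between tissues 1.94 ± 0.40, SE, n = 4), Myo18a (1.36), Synj2 (1.61), Flrt1 (2.17), Arhgap27 (2.47), the Notch ligand gene Jag2 (3.04), Caskin2 (1.63), Rreb1 (1.10) and the kinesin genes Kif3c (1.89) and Kif7 (1.83). Those with a lower effect in aorta included Faah, which encodes an enzyme that degrades endocannabinoids (−2.22 ± 0.50), the hyaluronan synthase gene Has1 (−1.35), Hgfac (−2.53), Copz1 (−1.32), Gldc (−1.53), Comp (−4.13) and Mrpl48 (−1.78), and the liver secretory genes Ttr (−1.62), Plg (−1.55) and Serpinc1 (−1.65). Pgr differed by 4.09 ± 1.46 and Esr1 by 0.14 ± 0.34.

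The interaction covered 14190 genes, the smallest adjusted p was 0.218, for Sfrp4, and 761 genes had an unadjusted p under 0.05, where 709.5 are expected by chance (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment); DESeq2 called 12 genes and limma voom 0. The Pgr value rests on liver libraries with few counts, and without the suffix o2 it was −2.27.

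Of the 36 lists, 6 passed camera with the preset correlation for the difference between tissues, and none with an estimated correlation (adjusted p between 0.56 and 0.938) or with fry. Hepatocyte genes (32 of 35 lower in aorta, median −0.87, 6 past the threshold adjusted over the list alone, with Ahsg at −1.04 ± 0.33), acute phase genes (29 of 34, median −0.70, 2 past the threshold adjusted over the list alone, Serpinc1 and Plg) and lipoprotein genes (18 of 23, median −0.53) had lower E2 effects in aorta. So had cytosolic ribosomal protein genes (28 of 31, median −0.67) and mitochondrial respiratory chain genes (25 of 30, median −0.23). In aorta itself only 24 hepatocyte, 23 acute phase and 20 lipoprotein genes passed the filter. The other members entered through liver, so their aortic effects rest on few counts. Liver RNA carried into the aorta libraries stays open for the hepatocyte genes. Fatty acid and triglyceride synthesis genes had higher effects in aorta (22 of 23, median 0.33). The length and GC correction was not run for these lists or for the correlation between tissues below. The E2 effect rose with transcript length in aorta (Spearman's rho 0.249) and fell with it in liver (−0.292). With the correction the ribosomal and mitochondrial lists lost their call in liver, while the ribosomal list kept its call in aorta. Adipocyte markers did not pass (16 of 24 higher, median 0.41), although Cidea (2.84 ± 0.79), a lipid droplet gene of brown fat, and the fatty acid elongase gene Elovl3 (2.04 ± 0.60) passed adjusted over the list alone. In the o libraries alone the value of Cidea was 0.30. Across 11118 genes tested in both tissues, which share no library, the E2 effects had a Pearson r of −0.057 (−0.178 at an average log2 CPM of 3 or more), and no gene with an unadjusted p under 0.01 moved the same way in both, where 0.139 shared higher and 0.0712 shared lower genes are expected of independent lists.

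Aorta and liver with vehicle were compared. Of 12607 genes tested, 3032 were higher and 2954 lower in aorta, past both thresholds (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Smooth muscle contractile genes rose in 19 of 21 tested members (median log2 difference 4.49): Myocd, the gene of the smooth muscle regulator myocardin, by 6.69 ± 0.46, Synpo2 by 6.57, Lmod1 by 5.83 and Tagln by 4.45. Adventitial fibroblast markers were higher in 14 of 19, with Mfap5 at 7.65 and Pi16 at 6.86. Adipocyte markers were higher in 16 of 24 and lower in 5, with Adipoq at 9.64, the brown fat gene Ucp1 at 7.51 and Cidea at 6.72, and the muscle genes Ryr2 and Casq1 were at 7.70 and 3.65. All 35 hepatocyte genes tested were lower in aorta (median −10.09), among them Serpina1a (−10.23 ± 0.48) and Hpx (−10.20 ± 0.51).

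Markers of other cell types differed too. Liver sinusoidal endothelial markers were lower in aorta in 15 of 17 and macrophage markers in 10 of 23, with the Kupffer cell genes Clec4f at −9.94 and Vsig4 at −6.88, while Lgals3, a macrophage galectin gene, was at 2.43. General endothelial markers went both ways, 4 of 22 higher and 6 lower, with Erg at 2.56, Plvap at −2.67, Kdr at −2.24 and Eng at −2.05. Extracellular matrix genes were higher in aorta in 26 of 36, hypoxia and glycolysis genes in 22 of 27, and bile acid and sterol export genes were lower in 21 of 24. The estrogen receptor gene Esr1 was lower in aorta, at 7.79 ± 4.62 against 18.1 ± 13.5 CPM in liver (SD, n = 4; log2 −1.16 ± 0.34, adjusted p 0.0122, edgeR), and lower in 4 of 4 suffixes. Pgr was higher in aorta (2.85 ± 0.96, adjusted p 0.0259, edgeR, 4 of 4), and Nrip1 did not pass (1.04 ± 0.42). The Esr1 call held in 16 of 25 other settings and the Pgr call in 13 of 25. Without the batch term their adjusted p were 0.206 and 0.374 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Plvap, Eng and Erg did not pass either. Factors known to open chromatin for estrogen receptor were lower in aorta, Foxa1 by −9.21, Foxa2 by −8.06 and Gata4 by −5.02. Camera with the preset correlation passed for 23 of 36 lists (9 higher, 14 lower), and with an estimated correlation for 1, the bile acid list (adjusted p 0.0378). Folds against genes with almost no counts in 1 tissue depend on the prior count, and without the batch term 2447 genes passed.

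Libraries n and o of the same tissue differed in 8360 of 13698 genes tested in aorta and 8147 of 11726 in liver. In aorta 4514 genes were higher and 3846 lower in n libraries, and in liver 3957 were higher and 4190 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rn45s was lower in n, by −1.08 ± 0.24 in aorta and −3.10 ± 0.34 in liver (log2, SE, n = 4). Cytosolic ribosomal protein genes had a median difference of 1.21 in aorta and 2.88 in liver, mitochondrial respiratory chain genes 0.55 and 2.03, and replication-dependent histone genes −1.14 and −0.88. The E2 effect was compared between n and o libraries by an interaction: no gene passed in aorta (126 of 13698 with an unadjusted p under 0.05, where 684.9 are expected) or in liver (1463 of 11726, where 586.3 are expected). Across genes the E2 effects in o and n libraries had a Pearson r of 0.257 in aorta, with 57.9% of genes of the same sign, and −0.096 in liver (−0.145 at an average log2 CPM of 3 or more), with 45.2%. With E2 and vehicle swapped within pairs, r was 0.097, 0.276 and 0.162 in aorta and between −0.09 and −0.051 in liver. The sign of a swapped r depends on which pair of a letter is swapped.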

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

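Chosen only after the results had been seen were the striated muscle test, taking the blocked aorta fit as a result of its own, and the correction for transcript length and GC content. The liver RNA test was rewritten when the shares of liver-enriched genes lower with E2 were known but its correlations were not, and its earlier version was dropped without being run. A pattern of histone and poly-A transcripts was also dropped. Which splits the E2 results are set beside was also chosen after their counts had been seen. The rule that a value must pass its bound by its spread over 500 resamplings of the genes was added after the values had been seen, and it left open a length trend in liver that its bound alone would have excluded.

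The 12 genes that passed in aorta with the replicate block moved the same way in all 4 pairs. Striated muscle carried along with E2 aortas is argued against, since the highest of the 4 pairs' median differences of the striated muscle list was 0.27 (log2), while the genes' median absolute change was 1.49. A trend with transcript length and GC content is argued against as the whole cause, since all 12 stayed past the threshold with the trend removed in the same blocked fit, at a median of 96.3% of their log2 fold change. Without the pair n2, whose vehicle library holds lymphocyte transcripts, the median absolute change was 92.9% of its value. The 12 genes were picked by a fit over the same 4 pairs, which favours genes whose pairs agree. Neither this value nor the shared direction can therefore exclude that library as a cause. Of the 8 splits of the libraries that part all 4 pairs 1, the real one, called as many as 12 genes and the highest other called 0, which is too few splits for a share under 0.05, and an E2 response of these genes is a hypothesis.

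Hepatocyte transcripts were lower with E2 in aorta. A trend with transcript length and GC content is argued against as the whole cause: with it removed the list's median was −0.55 (SD 0.123 over resampled genes), with 22 of 24 members lower. Different amounts of liver RNA carried into the aorta libraries stay open. The test used 48 liver-enriched genes (at least 1000 CPM in vehicle liver, less than 1 part in 50 of that in aorta). Across them the correlation of an aorta library with the liver profile was 0.494 at its lowest, between the bounds of 0.3 and 0.6 set for the test. It was 0.881, 0.679, 0.630 and 0.643 in vehicle o1, o2, n1 and n2, and 0.819, 0.572, 0.551 and 0.494 with E2. No library came under the lower bound, and every vehicle library lay above the upper one. These genes' median share of their liver level was 0.453%, 0.125%, 0.0411% and 0.0576% in vehicle o1, o2, n1 and n2. With E2 it was 0.248%, 0.0776%, 0.0309% and 0.0242%. An effect of E2 on cells of the aorta also stays open, as untested.

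The E2 effects in o and n libraries of liver ran against each other across genes (r = −0.096). With the length and GC trend removed r was −0.0840 (SD 0.0111 over resampled genes), and without the E2 library n2, the least sequenced of all, it was −0.0610 (SD 0.0115). Both values lie between or too close to the bounds of −0.08 and −0.03 set for the tests, so neither explanation is excluded. With labels swapped in o1 and n1, which leaves no E2 contrast in either letter, r was −0.0535. With labels swapped in o1 alone, which leaves none in the o libraries, r was −0.090. The sign of a swapped r depends on which pair of a letter is swapped, so only its size can be compared. A value near the size of the real one thus does not need an E2 contrast in the o libraries. Any difference in kit, RNA input or number of mice between o and n libraries cannot be told apart from the letter itself.

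Other splits of the libraries were run for each count of calls. A split that keeps a pair or batch whole leaves it to the covariate: the highest count of the blocked aorta fit outside the 8 splits above, 88, is E2 against vehicle in the pairs o2 and n2, and that of the blocked liver fit, 53, is E2 against vehicle in n1 and n2. That of aorta without the block, 322, mixes E2 against vehicle in o2 with the vehicle library n2 against the other n libraries. Such splits hold the E2 contrast in part, so the E2 results are set beside splits that part all 4 pairs, or in unpaired liver fits halve every batch. For the 12 lists called in aorta, 3 of 8 such splits, the real one among them, gave as many (highest other 14). For the 5 in liver 7 of 12 did, the real one included (highest other 17). Other groupings of the libraries thus gave as many called lists as E2 against vehicle. The number of called lists is therefore no evidence of an E2 effect in either tissue. A count of 0 genes is matched by every split, so the splits say nothing of the 0 in aorta (8 of 8, highest other 0), in liver (12 of 12, highest other 1; 8 of 8 with the block, highest other 2) or in the interaction (55 of 55 drawn splits, highest other 16). For aorta against liver 1 of 34 splits, the real one, called as many as 5986 genes, and the highest other called 0. For n against o libraries 1 of 34 did so in aorta (8360 genes) and 1 of 34 in liver (8147), each with a highest other of 0. Every other split mixes the tissues or the letters within a group, so their large difference enters the spread and leaves few calls. These splits therefore cannot exclude chance.

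A library lay far from the other 3 of its group in 9 of 188 groups of values tested, where 9.4 are expected by chance at 1 in 20. That expectation assumes independent values from a single normal distribution. Each group mixes o and n libraries, and the genes are not independent. The nearness of 9 to 9.4 therefore does not show that outlying libraries were as rare as chance would make them. In library values these were the low total of the E2 aorta o1 (6471319 counts), its high Rn45s share (6.12%), and the high total of the vehicle liver o2 (13078032 counts). In gene levels they were Alb (300.6 CPM), Plg (6.28 CPM) and Fgb (27.6 CPM) in the vehicle aorta o1, Fgb in the E2 aorta o1 (15.5 CPM), Cd79b (20.6 CPM) in the vehicle aorta n2, and Kif3c in the E2 liver n1 (5.13 CPM).

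The E2 effect differed between aorta and liver, by camera with the preset correlation, for hepatocyte genes (median of aorta minus liver −0.87), fatty acid and triglyceride synthesis genes (0.33), lipoprotein genes (−0.53), acute phase genes (−0.70), mitochondrial respiratory chain genes (−0.23) and cytosolic ribosomal protein genes (−0.67). None of these lists passed with an estimated correlation (adjusted p between 0.56 and 0.938, camera with Benjamini-Hochberg adjustment) or with fry. The limits given with these lists above, few aortic counts and no length and GC correction, hold here too. In blocked fits, whose pairing the n libraries of liver do not support, it differed between tissues for Sfrp4 (−4.45), and between n and o libraries of liver for Nnmt (2.92) and Orm2 (3.80). By suffix the difference of Sfrp4 was −1.35 in o1, −4.34 in o2, −1.38 in n1 and 0.32 in n2, so its direction was not shared.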

How the results depend on the processing

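The blocked aorta result with its settings, library totals, the length and GC correction and lists without n2 were chosen after the data had been seen. Among 136 named results, 3859 of 3883 alternative values kept their direction and 24 reversed. Apart from the genes always named, these were picked mostly for a shared direction in all suffixes or a small p. The alternative settings reuse the same libraries, so that choice favours kept directions. The count of kept directions is therefore no evidence that the results are robust. Depth limits low genes: Greb1 and Pgr in liver had too few counts for a test. The cause of the changes below was not tested, except that the list tests differ in what they assume and that leaving out n1 or n2 makes the batch equal to the block.

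Calls in aorta went from 0 to 12 with the replicate block, 24 with DESeq2, 2 at an adjusted p under 0.10 (Caskin2 and Pgr), 33 in o libraries alone (0 in n alone) and 4 with the length and GC correction, and to 0 to 35 with a library or suffix left out (35 without n2, 11 without n1, 17 without the vehicle n2). Calls in liver went from 0 to 6 with no filter, 5 in o alone, 1 in n alone, and 0 to 1 with a library or suffix left out (1 without o2, or without either liver o2). For the interaction they went from 0 to 1 with the block, 12 with DESeq2, 2 in o alone, and 0 to 4 on leaving out (4 without the aorta vehicle n1). Between tissues 5986 became 2447 with no batch term and 5053 to 6011 on leaving out. With the block itself 12 calls became 72 with no filter, 92 with DESeq2, 20 with robust fitting, 21 with voom, 22 at 0.10, 5 in 1 fit over all libraries and 19 with length and GC correction, and 0 (without o2) to 35 (without n2) on leaving out. Library totals kept 9 of the 12 in 9 calls. Of the 12 genes, 5 were among the calls of the single fit and 0 among those without o2. Each other setting named here called all 12, and leaving out o1 or n1 kept 9 of them. The E2 effect in n minus o libraries of liver gave 2 calls with the block and 2 with DESeq2 size factors, against 0. In the comparisons of E2 the block changed no other gene call.

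Lists called in aorta (12), liver (5) and the interaction (6) became 0 in each with an estimated correlation and 0 in each with fry. With the block those of aorta became 15, adding striated muscle, hypoxia and glycolysis, and clock genes, those of liver stayed 5, and those of the interaction became 10, where the suffix is not shown to pair the n libraries of liver. Those of liver became 3 with the length and GC correction (2 shared, without lipoprotein, mitochondrial and ribosomal lists) and 3 without n2 (1 shared, macrophage markers). Those of aorta became 11 with the correction (10 shared, without macrophage and gluconeogenesis lists) and 17 without n2 (10 shared, without lymphocyte and cell cycle lists).

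Most reversed directions belong to small values; Pgr in the interaction (4.09) and lymphocyte markers in aorta (−1.33) are large values that rest on few libraries. Esr1 in aorta was −0.088 in n alone and −0.0064 to 0.31 on leaving out, and Gper1 −0.40 to 0.060. In liver Esr1 was −0.0032 with no batch term, −0.029 in o alone, −0.17 with library totals and −0.074 to 0.070 on leaving out. Apom was −0.043 in o alone. Nrip1 was 0.0020 with length and GC correction, 0.036 with the block as well and −0.30 to 0.016 on leaving out. For the interaction Pgr was −1.48 in n alone and −2.41 to 6.00 on leaving out (−2.27 without o2), and Esr1 was −0.14 in n alone and −0.0098 to 0.35 on leaving out. List medians reversed in aorta without n2 (lymphocyte 0.036, cell cycle 0.077) and in liver in o alone (lipoprotein −0.13, mitochondrial −0.16, ribosomal −0.0039). Library totals move the median of all liver genes from −0.0053 to −0.21, and on that scale the 3 lists higher in liver stay above 0, at 0.01 (lipoprotein), 0.03 (mitochondrial) and 0.06 (ribosomal), and above that median.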

Other observations

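Values of E2 against vehicle for vessel-wall genes of the aorta follow. Of 22 smooth muscle contractile genes 17 were higher (median log2 difference 0.09). Of 22 endothelial markers 14 were lower (median −0.08), with the endothelial transcription factor gene Sox18 at 0.95 ± 0.25 and the tight junction gene Cldn5 at −0.84 ± 0.23, each in the same direction in 4 of 4 pairs. Among 34 genes of vascular tone and protection (16 higher, median −0.06), the alpha-adrenergic receptor gene Adra1d was at 1.17 ± 0.28 (higher in 3 of 4 pairs), the endothelin gene Edn1 at 0.74 ± 0.27 (4 of 4) and the heme oxygenase gene Hmox1 at −0.47 ± 0.16 (lower in 4 of 4). Clock genes were higher in 15 of 23 (median 0.09), with Cry2 at 0.80 ± 0.25 and Npas2 at 0.61 ± 0.22. Without the replicate block none of these lists passed camera. With it the clock list passed (median 0.12, adjusted p 0.0469, camera with Benjamini-Hochberg adjustment; 0.589 with an estimated correlation), and so did hypoxia and glycolysis genes (20 of 29 higher, median 0.12, camera adjusted p 0.0495; 0.565 with an estimated correlation). None of these genes passed over all genes tested in either fit.

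Striated muscle genes in aorta had a median of −0.24 over 19 members, with Ttn, the titin gene, at −1.41 ± 0.41 and lower in 4 of 4 pairs, and that list passed camera with the replicate block only (adjusted p 0.0469 with Benjamini-Hochberg adjustment, and 0.662 with an estimated correlation). Immediate early genes had a median of 0.01 in aorta and 0.13 in liver, and heat shock and unfolded protein response genes 0.0022 and 0.08. Interferon-stimulated genes had a median of 0.10 in aorta and −0.08 in liver, and cholesterol synthesis and uptake genes 0.13 and 0.15. Hepatocyte genes in liver itself had a median of 0.16, at −0.30 in o libraries alone and 0.55 in n libraries alone.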
